A study of Mus musculus with 6 samples.

How the data were processed

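Gene expression was measured by RNA sequencing in 6 samples of murine 10T1/2 cells activated with TGF-β at 5 ng per mL, 3 given PBS and 3 given photodynamic therapy (PDT) with chlorin e6 in midkine-directed extracellular vesicles followed by light. Groups were taken from the treatment named in the labels and replicate numbers from the sample titles. Per the labels' protocols, total RNA was extracted with Trizol, ribosomal RNA was removed, and libraries were made with a directional kit and sequenced as read pairs on an Illumina instrument. The deposited table holds whole-number read counts per gene symbol for each sample, not normalised, and per the submitters' processing notes cutadapt 4.6, STAR 2.7.11b and the genome build GRCm39 were used. The role and settings of these tools, the counter, the annotation, the use of strand and the treatment of reads that match several genes are not given in the sources used here. Without them, counts of genes with near-identical copies, of overlapping genes and of antisense partners are uncertain. Whether a read pair was counted once or per mate is not given either, so totals are stated as counts. The time between treatment and extraction is also not given in the sources used here.

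The table has 57180 rows, of which 29921 had a count in at least 1 sample, and 0 rows named no gene. Totals ran from 83195529 to 99527847 counts per sample. A count of 0 allows up to 3 counts, which is 0.0301 to 0.0361 CPM per library, and such limits cover counting error only. Because the annotation used here is of another genome build than the counts, no coordinates are given, and genes are identified by the symbols of the table. Ddit3 and the list members Sars1, Aldoa, Atp5po and Rmrp were not analysed here.

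Genes were filtered with filterByExpr at its defaults, which left 17635, and libraries were scaled with TMM. PDT was compared with PBS with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, on group alone with no block, and p-values were adjusted by Benjamini-Hochberg over all tested genes with a threshold of 0.05. The SE of a log2 fold change was taken as its size divided by the square root of the F statistic. The common biological coefficient of variation was 10%. Levels are CPM with TMM-scaled library sizes, and log2 CPM used a prior count of 2. The count of genes changed at least 2-fold is a description and not a test against that fold. Principal components and correlations were computed on log2 CPM of the tested genes.

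There were 41 gene lists, written before the data were examined, and 39 had at least 5 tested members. Each was compared with all other genes with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry, which tests whether a list's genes move on balance in 1 direction and does not compare them with other genes. Counts of changed members are given over all genes and adjusted over the list alone. Named genes were chosen by a rule fixed beforehand: the 10 called genes with the highest and the 10 with the lowest log2 fold change among those with an average log2 CPM of at least 2, no overlap between the groups and a symbol that is not of a predicted or unnamed gene; up to 4 called members of each list with the lowest adjusted p; and a fixed set of fibroblast, matrix, stress and proliferation genes together with Mdk. Some genes that this rule selects are not reported here. Other genes are marked as chosen after their values were seen.

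The alternatives planned before the data were examined were RLE scaling, library size only, DESeq2 1.42.0, limma-voom, no low-count filter, a stricter filter (at least 10 counts in 3 samples and a mean of at least 1 CPM), removal of mitochondrial, ribosomal RNA and histone genes, the replicate number as a block, leaving out each sample in turn, and the 2 other list tests. Offsets for transcript length and GC content were added after the data were seen. For these, the longest protein-coding GENCODE M21 transcript of each symbol gave its length and GC content, or the longest transcript where none was protein-coding. This covered 16356 (92.7%) of the tested genes, and a smooth of each library's deviation on length and GC was fitted with mgcv 1.9.3. The annotation is of an earlier build, so it was used for gene properties only. The replication-dependent histones had no matching symbols there, so their check with offsets is void.

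The procedure was tested on simulated counts for 17206 genes in 3 and 3 libraries. Of 100 genes changed 1.2-fold 27% were recovered, of 100 changed 1.5-fold 80% were recovered, and 3 unchanged genes were called. A list shifted by -0.3 was called and 0 of 37 other lists were. Genes were simulated independently of each other, so list calls under correlation between genes were not tested. The recovery simulation changed 200 genes, against 36.1% of the tested genes called in the data, so its rates need not carry over. A simulated slope of -0.1 in log2 fold change per doubling of length was -0.0989 in the fit without offsets and 6.64e-05 with them. The offsets are fitted on length in each library, so this removal follows from the method. It does not show whether a trend in the data is technical. Changed genes were drawn without regard to length, so lists whose members share a length or GC content were not tested.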

Results

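Transcript levels were measured by RNA sequencing in murine 10T1/2 cells, a mesenchymal fibroblast line. The cells had been stimulated with TGF-β as a model of cancer-associated fibroblasts (CAFs), and their likeness to CAFs was not tested here. All samples were given TGF-β, so the response to TGF-β itself was not measured. There were 6 libraries, 3 from control cells given PBS and 3 from cells given photodynamic therapy (PDT). In PDT a dye is excited by light and passes the energy to oxygen, which yields reactive oxygen species. The dye here was chlorin e6, carried by extracellular vesicles directed at midkine (MDK), and it was applied before light irradiation. The PBS libraries held 86558216, 83195529 and 83259317 counts and the PDT libraries held 88669946, 99527847 and 97954533. Between 23284 and 24337 genes had at least 1 count per library, and mitochondrially encoded genes took 2.24% to 2.57% of the counts. Levels are given as normalised read counts (CPM) ± SD over 3 libraries, and log2 fold changes, PDT against PBS, are given ± SE. Adjusted p-values of single genes are from the quasi-likelihood test of edgeR with Benjamini-Hochberg adjustment.

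The groups lay apart on the first principal component, which held 43.8% of the variance. The PBS libraries had scores of -35.9 to -32.9, and the PDT libraries had scores of 39.9, 38.9 and 23.7 for replicates 1, 2 and 3. Across genes, log2 CPM correlated with r of 0.9881 to 0.9899 between libraries of 1 group and 0.9809 to 0.9839 between groups, and genes are not independent replicates. Over 5493 changed genes, the fold changes of PDT replicate 3 had a slope of 0.835 on the mean of the other PDT libraries, while replicates 1 and 2 had slopes of 1.05 and 1.07. No pair of libraries agreed within sampling noise (chi-square per degree of freedom of at least 10.3), so none was treated as a copy of another.

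The comparison of PDT with PBS asked which transcripts differed after treatment of the activated fibroblasts, with TGF-β signalling and extracellular matrix programs as the stated interest. Genes of the TGF-β response and of the matrix were among those that fell in PDT. Pmepa1, a TGF-β-induced inhibitor of SMAD signalling, fell 13.5-fold from 69.6 ± 1.88 to 5.14 ± 0.52 CPM, and Ccn2, a matricellular TGF-β target, fell 6.98-fold from 269.6 ± 15.4 to 38.7 ± 2.95. Col1a1, the α1 chain of collagen I, fell 2.48-fold from 6025 ± 178 to 2428 ± 12.1 CPM. Inflammatory and antioxidant genes were among those that rose. The neutrophil chemoattractant Cxcl1 rose 6.15-fold from 21.7 ± 1.82 to 133.6 ± 4.58 CPM, and Hmox1, the heme-degrading oxygenase, rose 1.67-fold from 96.2 ± 2.13 to 161 ± 4.64. As groups, genes of glycolysis and the hypoxia response were lower (median log2 fold change -0.31, camera adjusted p = 4.7e-07) and nuclear genes of oxidative phosphorylation were higher (0.26, 2.1e-08; 0.14 and 8.9e-06 with length and GC offsets). Neither call held with an estimated correlation (adjusted p = 0.22 and adjusted p = 0.30 with an estimated correlation). Mdk itself, the gene of the protein the vesicles were directed at, had 17, 11 and 15 counts in PBS and 6, 11 and 10 in PDT. Its level was 0.17 ± 0.03 CPM in PBS and 0.09 ± 0.02 in PDT, and the CPM of the groups did not overlap. A difference was not detectable at this low level (log2 fold change -0.89 ± 0.48, adjusted p = 0.182).

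Of 17635 genes tested, 6372 (36.1%) changed, 3294 of them higher and 3078 lower in PDT. At least 2-fold changes were seen for 610 genes, 225 higher and 385 lower, and for 276 genes with a stricter low-count filter. With scaling by library size only, 4290 genes were called higher and 2517 lower, and the share of calls that were higher was 63% in place of 51.7%. The samples are stated to be biological replicates, but separate cultures or days are not described, so p-values measure the spread between these samples. Vesicles, dye and light were given together, and samples with only some of them were not analysed here.

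The 10 genes with the greatest decreases had log2 fold changes of -3.76 to -2.60, with adjusted p of 4.02e-07 or less. After Pmepa1 came Sertad4 (-3.63 ± 0.06, 74.8 ± 0.78 to 6.05 ± 0.39 CPM) and Sorbs2, an adaptor of the actin cytoskeleton (-3.49 ± 0.11, 17.3 ± 1.60 to 1.54 ± 0.17 CPM). Asporin (Aspn), a small leucine-rich proteoglycan, fell by 3.25 ± 0.08 from 191.5 ± 11.2 to 20.2 ± 2.17 CPM. Tnfrsf11b, which encodes the RANKL decoy receptor osteoprotegerin, fell from 336.5 ± 12.8 to 39.4 ± 1.18 CPM. Sulf1, an enzyme that removes sulfate groups from heparan sulfate, fell from 93.1 ± 1.54 to 12.0 ± 0.92 CPM. Gprin3, the annexin Anxa8 and the zinc finger gene Zfp469 completed these with Ccn2, at -3.18 ± 0.10, -3.02 ± 0.14 and -2.60 ± 0.06.

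Among the 10 genes with the greatest increases, Cxcl1 (2.62 ± 0.06) was followed by Saa3, an acute-phase serum amyloid (2.43 ± 0.15, 3.69 ± 0.33 to 19.8 ± 4.32 CPM). The chemokine Cxcl5 rose from 38.2 ± 5.73 to 148 ± 5.36 CPM, and Enpp2, the secreted enzyme autotaxin, rose from 11.3 ± 1.79 to 43.0 ± 4.46. The metal-binding metallothioneins Mt1 and Mt2 rose 3.26-fold and 3.44-fold, to 135 ± 11.1 and 95.4 ± 6.10 CPM. Col23a1, a transmembrane collagen, rose by 2.19 ± 0.12, Aldh1a7 by 2.05 ± 0.06 and Atf3, a stress-induced transcription factor, by 1.58 ± 0.10. Adjusted p was 3.04e-06 or less for these 9 genes. Pagr1a also passed the test (2.25 ± 0.53, adjusted p = 0.00859), but PDT replicate 3 held 15.1 CPM against 3.33 and 3.75 in the others, and its adjusted p was 0.0619 by limma-voom. Aldh1a7 and Pagr1a have close homologues, and because the counting of reads that match several genes is not described, their levels are uncertain.

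**Figure D1:**
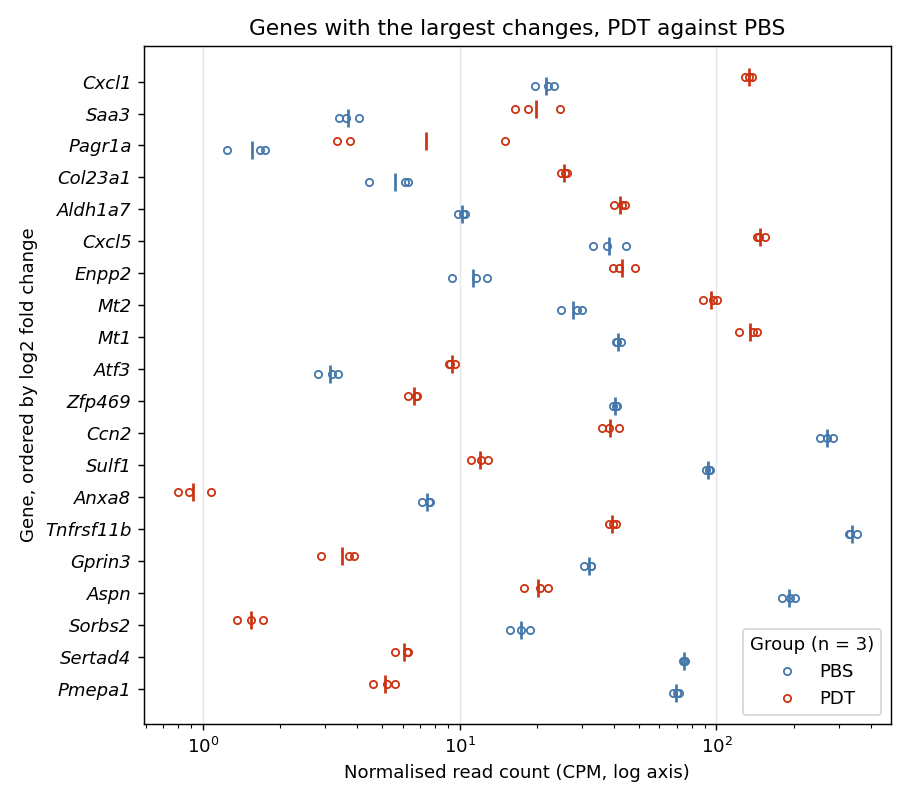
Normalised read counts (CPM, log axis) of the 10 genes with the greatest increase and the 10 with the greatest decrease in PDT. Open circles are single libraries, blue for PBS and red for PDT (n = 3 each), and vertical marks are group means. Within each gene the circles of the groups do not overlap, and for Pagr1a 1 PDT library lies at 15.1 CPM, apart from 3.33 and 3.75.

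Fold changes varied with transcript length and GC content. Over 9172 protein-coding genes with an average log2 CPM of at least 3, log2 fold change had a Spearman rho of -0.35 with transcript length and 0.38 with GC content, across genes, which are not independent replicates. When these genes were divided into 10 equal bins, the bin of the shortest transcripts (median 1054 nt) had a median log2 fold change of 0.16 and that of the longest (8380 nt) had -0.17. The bin lowest in GC (median 40.1%) had -0.23 and the highest (59.5%) had 0.13. Medians of the lists called by camera, apart from the histones, are therefore given also with per-library offsets for length and GC, chosen after seeing the data. With these offsets 5484 of 16356 genes were called, against 6137 without them on the same genes, and 4412 were called both ways in the same direction. Because the trend lies between the groups, the offsets also take out any treatment effect that follows length or GC. A call that ended with them is therefore not shown to be an artifact.

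**Figure D2:**
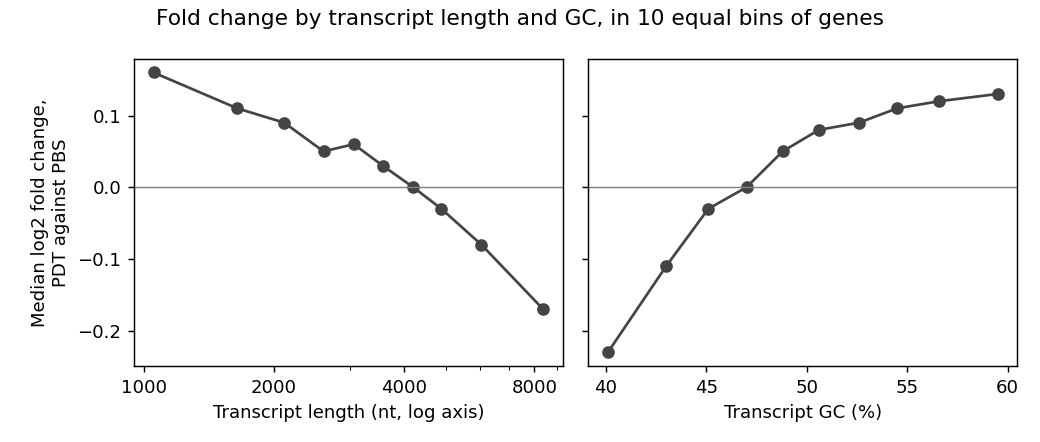
Median log2 fold change, PDT against PBS, of 9172 protein-coding genes (average log2 CPM of at least 3) divided into 10 equal bins by transcript length (left, nt on a log axis) and by GC content (right, percent). Each point is a bin at its median length or GC: the median fold changes run from 0.16 for the shortest to -0.17 for the longest, and from -0.23 for the lowest to 0.13 for the highest GC.

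Gene lists fixed before the data were examined were compared with all other genes by camera. Of 39 lists with at least 5 tested genes, 23 were called, 8 higher and 15 lower, and 20 were called with length and GC offsets. None of the 23 calls held with an inter-gene correlation estimated from these 6 libraries, where the lowest adjusted p was 0.098, while the self-contained test fry called 30 lists. Of these, 8 were not called by camera, namely matrix proteases, metallothioneins, p53 targets, immediate early genes, heme synthesis, midkine receptors, Wnt and Notch targets, and leukocyte markers, and fry did not call the ribosomal proteins (adjusted p = 0.13).

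Direct TGF-β target genes had a median log2 fold change of -0.47 (-0.54 with length and GC offsets), with 17 of 24 tested members lower and 2 higher (17 and 3 adjusted over the list alone). The camera test gave adjusted p = 2.4e-08, and adjusted p = 0.098 with an estimated correlation. Beside Pmepa1 and Ccn2, the integrin subunit gene Itgb5 fell by 1.12 ± 0.04, from 304.9 ± 3.85 to 139.9 ± 2.59 CPM. Among 30 components of TGF-β and BMP pathways 17 fell and 3 rose (19 and 4 adjusted over the list alone), with a median of -0.24 (-0.13 with offsets) and camera adjusted p = 0.00031, or adjusted p = 0.25 with an estimated correlation. Thrombospondin 1 (Thbs1), an activator of latent TGF-β, fell 4.61-fold from 3967 ± 100 to 860.1 ± 36.1 CPM, and the ligand genes Bmp4 and Inhba fell by 1.35 ± 0.05 and 0.92 ± 0.06. Smad6, an inhibitory SMAD, fell by 0.96 ± 0.07. Tgfb1 rose by 0.33 ± 0.07, from 9.99 ± 0.35 to 12.5 ± 0.44 CPM (adjusted p = 0.00496).

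Of 28 myofibroblast and contractile genes, 18 fell and 2 rose (18 and 2 adjusted over the list alone). Their median was -0.23 (-0.25 with offsets), with camera adjusted p = 0.00046 and adjusted p = 0.29 with an estimated correlation. Acta2, which encodes α-smooth muscle actin, fell 1.25-fold from 4381 ± 252 to 3513 ± 79.3 CPM (-0.32 ± 0.05, adjusted p = 0.000538), a smaller change than in Tagln (transgelin, -0.92 ± 0.06) or Cald1 (caldesmon, -0.88 ± 0.04). The non-muscle myosin gene Myh10 and the actin crosslinker gene Actn1 fell by 0.67 ± 0.04 and 0.47 ± 0.03. Fibroblast and CAF markers had 12 of 24 members lower and 5 higher, with the same counts adjusted over the list alone, and a median of -0.17 (-0.08 with offsets). Camera gave adjusted p = 0.027 for them, against adjusted p = 0.25 with an estimated correlation, 0.06 with offsets and 0.062 without PDT replicate 3. In this list periostin (Postn) fell 3.14-fold from 3516 ± 145 to 1121 ± 80.8 CPM, fibulin 2 (Fbln2) by 0.75 ± 0.04 and the transcription factor gene Snai1 by 1.07 ± 0.06, while podoplanin (Pdpn) rose by 0.75 ± 0.04. Fap, fibroblast activation protein, had 0 counts in all 6 libraries, which allows a level of up to 0.0301 to 0.0361 CPM per library (3 counts, counting error only).

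Of 22 collagen genes 13 fell and 2 rose (13 and 3 adjusted over the list alone), with a median of -0.56 (-0.50 with offsets). The camera adjusted p was 3.7e-05, and adjusted p = 0.22 with an estimated correlation. The fibril-associated collagen gene Col12a1 fell 4.88-fold from 1028 ± 15.6 to 210.6 ± 7.47 CPM, Col5a2 fell by 1.31 ± 0.04, Col3a1 by 1.04 ± 0.04 and Col1a2 by 0.92 ± 0.04. Matrix glycoproteins and proteoglycans had 24 of 36 members lower and 5 higher, also when adjusted over the list alone. Their median was -0.42 (-0.38 with offsets), with camera adjusted p = 5.1e-06 and adjusted p = 0.22 with an estimated correlation. Fbln5, an organiser of elastic fibres, fell by 2.21 ± 0.05, osteoglycin (Ogn) by 1.86 ± 0.06, Sparc by 0.87 ± 0.04 and fibronectin (Fn1) by 0.50 ± 0.04, whereas thrombospondin 2 (Thbs2) rose 2.00-fold from 154.3 ± 0.95 to 309.3 ± 7.96 CPM. Enzymes of matrix crosslinking and collagen processing had 15 of 23 members lower and 1 higher (16 and 1 adjusted over the list alone). This list had a median of -0.36 (-0.43 with offsets), camera adjusted p = 2.6e-06 and adjusted p = 0.22 with an estimated correlation. Lysyl oxidase (Lox), which crosslinks collagen and elastin, fell 4.03-fold from 4432 ± 20.6 to 1100 ± 42.6 CPM, the lysyl hydroxylase gene Plod2 fell by 1.65 ± 0.07, the procollagen-processing protease gene Tll1 by 1.71 ± 0.09 and the prolyl hydroxylase gene P4ha1 by 0.73 ± 0.04.

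Matrix proteases and their inhibitors were not called by camera (median 0, mean 0.07, test direction lower, adjusted p = 0.58) and were called by fry (adjusted p = 0.0015), and 8 of 29 members rose and 10 fell (9 and 10 adjusted over the list alone). Adamts12, Adamts5, Timp1 and Timp3 fell by 1.16 ± 0.06, 0.66 ± 0.04, 0.65 ± 0.04 and 0.55 ± 0.03. Integrin and focal adhesion genes had 14 of 29 members lower and 2 higher, as they did when adjusted over the list alone. Their median was -0.19 with and without offsets (camera adjusted p = 0.0014; adjusted p = 0.29 with an estimated correlation). Fermt2 (kindlin-2), Itgav and Tns3 fell by 0.69 ± 0.03, 0.62 ± 0.04 and 0.53 ± 0.04, and the laminin-binding integrin subunit Itga6 rose by 0.69 ± 0.05. Targets of the mechanosensitive coactivators YAP and TAZ had 9 of 20 members lower and 2 higher (10 and 2 adjusted over the list alone), with a median of -0.17 (-0.16 with offsets). Camera gave adjusted p = 0.0032 and adjusted p = 0.25 with an estimated correlation. Tissue factor (F3), Amotl2, Ajuba and Gadd45b fell by 1.25 ± 0.05, 0.61 ± 0.04, 0.67 ± 0.04 and 0.62 ± 0.04.

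Genes of the oxidative stress response, among them targets of its transcription factor NRF2, were higher as a list. Of its 32 members 25 were up and 2 down (26 and 3 adjusted over the list alone). Their median was 0.36 (0.31 with offsets), with camera adjusted p = 7.7e-08 and adjusted p = 0.25 with an estimated correlation. Beside Hmox1, the glutathione transferase gene Gsta4 rose 2.15-fold from 50.2 ± 2.49 to 108 ± 6.12 CPM, sulfiredoxin (Srxn1) rose by 0.71 ± 0.04 and the mitochondrial superoxide dismutase gene Sod2 by 0.84 ± 0.05. Among 5 genes of metallothioneins and the zinc response 3 rose and 1 fell, also when adjusted over the list alone. The group was not called (median 0.52, 0.60 with offsets, camera adjusted p = 0.064), although Mt1, Mt2 and the zinc exporter gene Slc30a1 (0.52 ± 0.07) rose. It was called by limma-voom (0.026), without the low-count filter (0.015), without PDT replicate 1 (0.04) and with offsets (0.014). The zinc importer gene Slc39a10 was at -0.16 ± 0.05 (adjusted p = 0.0392), a call that ended with library size only (0.133), without the filter (0.0898), with offsets (0.625) and without PBS replicate 1 (0.0853), PBS replicate 3 (0.135), PDT replicate 1 (0.0833) or PDT replicate 2 (0.104).

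Heat shock genes were not called as a group, with 8 of 21 higher and 6 lower over all genes and over the list alone (median 0.01, mean -0.07, test direction lower, camera adjusted p = 0.89). The small heat shock protein genes Hspb7 and Cryab fell by 1.94 ± 0.10 and 0.47 ± 0.06, Dnajb4 fell by 0.42 ± 0.04, and the mitochondrial chaperonin gene Hspd1 rose by 0.35 ± 0.04. Genes of the unfolded protein response and of ATF4 were lower, with 18 of 37 down and 5 up (21 and 5 adjusted over the list alone) and a median of -0.16 (-0.14 with offsets). Camera gave adjusted p = 0.0011 for this list and adjusted p = 0.29 with an estimated correlation. Its members Nupr1 and the endoplasmic reticulum chaperone gene Hsp90b1 fell by 1.29 ± 0.07 and 0.71 ± 0.04, while Atf3 and Cebpb rose by 1.58 ± 0.10 and 0.52 ± 0.04. Ddit3 was not analysed here. For p53 targets 9 of 26 rose and 6 fell (11 and 7 adjusted over the list alone), with a median of 0.04 and camera adjusted p = 0.38. Plk2 and Gadd45a rose by 0.75 ± 0.04 and 0.77 ± 0.06, Btg2 and Trp53inp1 fell by 0.40 ± 0.04 and 0.47 ± 0.05, and the cell cycle inhibitor gene Cdkn1a was at -0.12 ± 0.04 (adjusted p = 0.0231), a call that ended with library size only (0.128), without the low-count filter (0.06) and without PBS replicate 1 (0.0813), PBS replicate 2 (0.0799) or PDT replicate 2 (0.0784).

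NF-κB targets and inflammatory cytokines were higher, with 23 of 36 members up and 2 down, also when adjusted over the list alone. Their median was 0.50 (0.48 with offsets), with camera adjusted p = 1.3e-06 and adjusted p = 0.22 with an estimated correlation. Beside Cxcl1 and Cxcl5, lipocalin 2 (Lcn2), an iron-binding acute-phase protein, rose 2.55-fold from 34.2 ± 1.69 to 87.3 ± 2.37 CPM. The stromal chemokine Cxcl12 went the other way and fell 1.93-fold from 3456 ± 114 to 1788 ± 19.3 CPM. Markers of leukocytes stayed low in the same libraries: the pan-leukocyte gene Ptprc and Tyrobp had 0 counts in all 6 (up to 0.0301 to 0.0361 CPM per library), 5 of 14 markers were tested, and of these Cd68 rose from 0.86 ± 0.04 to 1.44 ± 0.06 CPM (also over the list alone). The tested leukocyte markers had a median of 0.18 and camera adjusted p = 0.28, with medians of 0.09, 0.05 and 0.77 in PDT replicates 1, 2 and 3 against PBS. Of 11 endothelial markers 3 were tested, none with a mean over the 6 libraries above 1.05 CPM, and Tek fell by 1.44 ± 0.39, a call that ended without PBS replicate 2 (adjusted p = 0.0848), PDT replicate 1 (0.0517) or PDT replicate 2 (0.0543). Of 12 epithelial markers 2 were tested, and the keratin gene Krt7 fell from 8.19 ± 0.55 to 2.87 ± 0.33 CPM.

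Antigen presentation and immunogenic signal genes had 12 of 19 members higher and 1 lower, also when adjusted over the list alone, and a median of 0.36 (0.37 with offsets). Camera gave adjusted p = 0.00077 and adjusted p = 0.28 with an estimated correlation. The MHC class I genes H2-K1 and H2-Q4 rose by 0.64 ± 0.06 and 0.53 ± 0.07, but such genes share sequence and their separate levels are uncertain. Annexin A1 (Anxa1) rose by 0.44 ± 0.04, to 2385 ± 28.8 CPM, and the immunoproteasome gene Psmb10 by 0.51 ± 0.08. Interferon-stimulated genes were not called as a group, with 11 of 44 higher and 6 lower over all genes and over the list alone (median 0.09, camera adjusted p = 0.23, and 0.04 without PDT replicate 1). Gbp2, Ifi203 and Ifit3 rose by 0.71 ± 0.06, 0.57 ± 0.06 and 0.54 ± 0.07, and Trim30a fell by 0.63 ± 0.05. Apoptosis genes had 9 of 28 higher and 7 lower (11 and 7 adjusted over the list alone), with a median of 0.10 and camera adjusted p = 0.48. Among the BH3-only genes of this list Bmf fell by 2.12 ± 0.11, from 9.65 ± 0.93 to 2.21 ± 0.11 CPM, while Bcl2l11 and Bid rose by 0.46 ± 0.05 and 0.42 ± 0.05. The caspase inhibitor gene Xiap fell by 0.34 ± 0.05, and with length and GC offsets it was at 0.11 (adjusted p = 0.148).

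Genes of glycolysis and hypoxia were lower, with 21 of 30 members down and 2 up (23 and 4 adjusted over the list alone). Their median was -0.31 (-0.32 with offsets), with camera adjusted p = 4.7e-07 and adjusted p = 0.22 with an estimated correlation. The hypoxia-inducible genes Bnip3 and Ankrd37 fell by 1.05 ± 0.04 and 2.56 ± 0.12, and Pdk1, a kinase that inhibits pyruvate dehydrogenase, fell from 169.1 ± 7.85 to 99.6 ± 5.76 CPM. Ndrg1, also hypoxia-inducible, rose by 0.62 ± 0.04. Nuclear genes of oxidative phosphorylation had 30 of 34 members higher and 0 lower (32 and 0 adjusted over the list alone), with a median of 0.26. The camera test gave this list adjusted p = 2.1e-08, or adjusted p = 0.30 with an estimated correlation. With offsets the median was 0.14, 17 of 29 members were higher and camera gave adjusted p = 8.9e-06. Ndufv1, Ndufb9 and Cox7c rose by 0.34 ± 0.04, 0.39 ± 0.05 and 0.37 ± 0.05, and the complex III gene Uqcrc1 by 0.28 ± 0.04. Of 15 mitochondrially encoded genes 6 fell and 0 rose, over all genes and over the list alone, with a median of -0.21. Their camera adjusted p was 0.0052, and adjusted p = 0.47 with an estimated correlation, but with offsets the median was 0.07 and the call ended (0.54). The mitochondrial ribosomal RNA gene mt-Rnr2 fell by 0.66 ± 0.08, but ribosomal RNA was removed before sequencing, so its level is uncertain. The complex I genes mt-Nd5, mt-Nd3 and mt-Nd4l fell by 0.38 ± 0.05, 0.34 ± 0.05 and 0.37 ± 0.08. With offsets mt-Nd5 and mt-Nd3 were no longer called (adjusted p = 0.371 and 0.485).

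Autophagy and lysosome genes were higher, with 19 of 32 members up and 1 down over all genes and over the list alone. Their median was 0.24 (0.22 with offsets), with camera adjusted p = 4.8e-05 and adjusted p = 0.29 with an estimated correlation. The lysosomal hydrolase genes Gla and Neu1, the cholesterol transporter gene Npc1 and the autophagosome gene Gabarapl1 rose by 0.82 ± 0.05, 0.64 ± 0.05, 0.62 ± 0.05 and 0.45 ± 0.04. Cholesterol and fatty acid synthesis genes had 11 of 33 higher and 5 lower (12 and 6 adjusted over the list alone), and a median of 0.10 that was not called (camera adjusted p = 0.077). This list was called with library size only (0.039), without the low-count filter (0.016) and without PBS replicate 2 (0.025). Mvd, Acly and Dhcr7 rose by 0.57 ± 0.07, 0.38 ± 0.05 and 0.44 ± 0.06, and Hmgcs1 fell by 0.30 ± 0.04. Heme synthesis and porphyrin transport genes had 7 of 15 higher and 2 lower over all genes and over the list alone (median 0.07, camera adjusted p = 0.17). The heme transporter gene Slc48a1 rose by 0.56 ± 0.05, and Alas1, the first enzyme of heme synthesis, by 0.26 ± 0.05, as did Alad by 0.26 ± 0.05.

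Genes of G2/M and of S phase were not called as groups. Of 41 G2/M genes 6 rose and 14 fell (6 and 15 adjusted over the list alone; median -0.02, camera adjusted p = 0.31), and Bub1, Kif11 and Ttk fell by 0.48 ± 0.05, 0.35 ± 0.05 and 0.33 ± 0.05 while Cdc25b rose by 0.29 ± 0.04. Of 41 S phase genes 8 rose and 8 fell over all genes and over the list alone (median 0.01, mean -0.01, test direction higher, camera adjusted p = 0.98), with Ccne2, Brca1 and E2f7 lower by 0.66 ± 0.06, 0.39 ± 0.06 and 0.50 ± 0.07 and Mcm2 higher by 0.27 ± 0.04. The proliferation marker gene Mki67 was at 266.6 ± 41.3 CPM in PBS and 174.6 ± 52.5 in PDT with overlapping libraries (-0.61 ± 0.18, adjusted p = 0.0242), and its call ended with DESeq2 (0.0746), without the low-count filter (0.0909), and without PBS replicate 1 (0.0561), PBS replicate 3 (0.103), PDT replicate 1 (0.0774) or PDT replicate 2 (0.0799). Replication-dependent histone genes had 8 of 26 lower and 0 higher, also when adjusted over the list alone, with a median of -0.40. Camera gave adjusted p = 0.0061 for them, and adjusted p = 0.25 with an estimated correlation. Without PDT replicate 3 their median was -0.25 and camera gave adjusted p = 0.066. H1f3, H2ac4, H1f2 and H2bc4 fell by 1.35 ± 0.16, 1.67 ± 0.29, 0.40 ± 0.06 and 0.40 ± 0.08, and histone genes have near-identical copies that make single levels uncertain.

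Cytosolic ribosomal protein genes had 17 of 45 members higher and 0 lower (18 and 0 adjusted over the list alone), with a median of 0.13 and camera adjusted p = 8e-04. The list gave adjusted p = 0.66 with an estimated correlation, and with offsets its median was 0.02 and the call ended (0.97). The medians against PBS were 0.18, 0.21 and 0.02 in PDT replicates 1, 2 and 3. Rps18, Rps14, Rpl38 and Rpl27 rose by 0.29 ± 0.04, 0.20 ± 0.04, 0.28 ± 0.06 and 0.16 ± 0.04, and with offsets none of the 4 was called (adjusted p of 0.0711 to 0.774). The Rpl27 call also ended without PDT replicate 1 (0.0578) or PDT replicate 2 (0.0584). Ribosomal protein genes, like Gapdh (63.0 ± 1.70 CPM in PBS and 56.6 ± 1.36 in PDT, chosen after its values were seen), have many processed pseudogenes, so their levels are uncertain. Noncoding RNA hosts and decay-sensitive transcripts had 4 of 15 higher and 4 lower over all genes and over the list alone (median -0.04, mean -0.02, test direction higher, camera adjusted p = 0.94). The nuclear noncoding RNAs Malat1 and Meg3 fell by 0.92 ± 0.19 and 0.83 ± 0.15, Snhg1 fell by 0.21 ± 0.05 and Epb41l4aos rose by 0.34 ± 0.09. The size of the first 2 falls differed between PDT replicates 1, 2 and 3. Malat1 held 754.6, 737.4 and 1284 CPM in them, and Meg3 held 73.47, 65.25 and 103.9. With offsets Snhg1 (adjusted p = 0.695) and Epb41l4aos (0.201) were no longer called, and the latter was not called without PDT replicate 1 (0.0653).

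Midkine receptors and partners had 2 of 8 members higher and 4 lower (3 and 4 adjusted over the list alone), with a median of -0.08 and camera adjusted p = 0.45. Lrp6, Notch2 and syndecan 2 (Sdc2) fell by 0.44 ± 0.05, 0.33 ± 0.04 and 0.28 ± 0.04 (Sdc2 at adjusted p = 0.0588 with offsets), and pleiotrophin (Ptn), the growth factor related to midkine, rose from 514.1 ± 39.7 to 694.6 ± 26.9 CPM. Extracellular vesicle cargo genes and tetraspanins had 4 of 13 higher and 2 lower over all genes and over the list alone (median 0.03, camera adjusted p = 0.58). Rab27b, a regulator of exosome secretion, fell by 0.49 ± 0.08, and Flot2, Sdcbp and Cd81 rose by 0.23 ± 0.04, 0.20 ± 0.04 and 0.21 ± 0.05. Of the 4, Rab27b and Cd81 were no longer called with length and GC offsets (adjusted p = 0.367 and 0.0655).

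**Figure D3:**
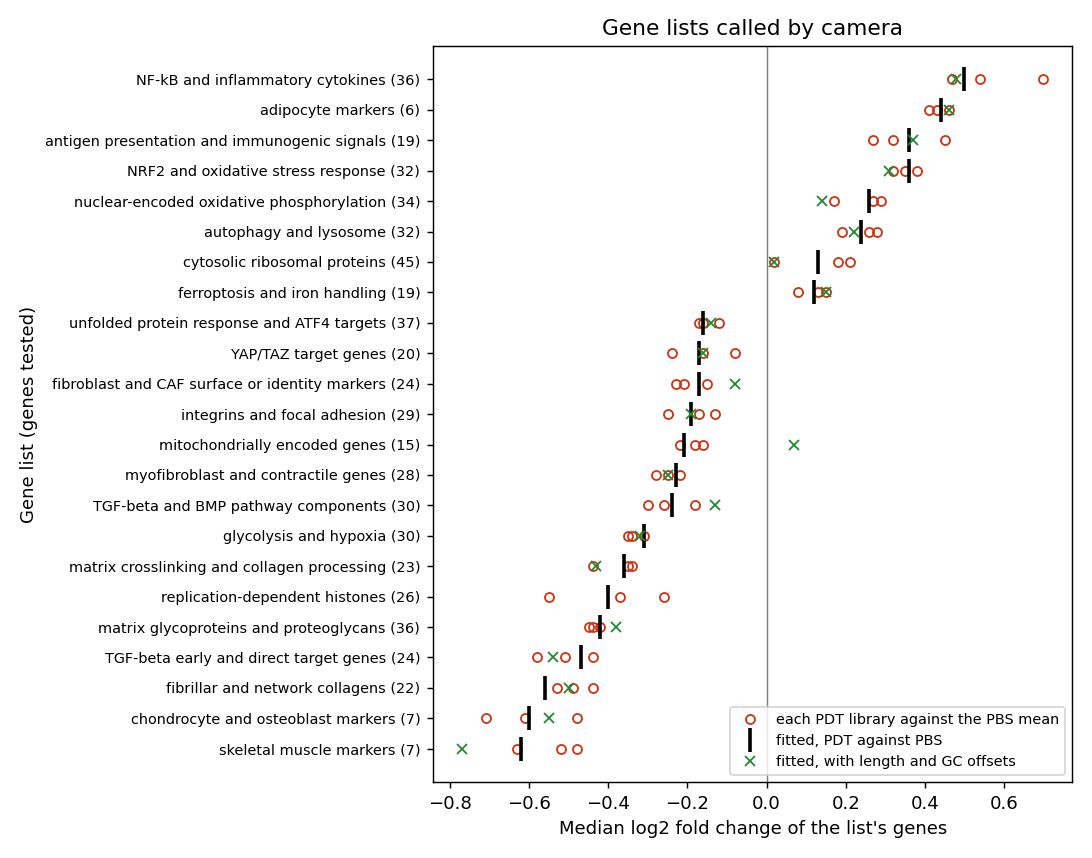
Median log2 fold change, PDT against PBS, of the 23 gene lists called by camera, ordered by the median, with the number of tested genes in parentheses. Black marks are the fitted medians, red circles each PDT library against the PBS mean (n = 3), and green crosses the medians with length and GC offsets, which move the mitochondrially encoded genes from -0.21 to 0.07 and the ribosomal proteins from 0.13 to 0.02. Histones have no cross, since their genes had no length or GC value.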

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

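The length and GC offsets were chosen after the data were seen, and all other settings before. The number of changed genes ran from 5300 without the low-count filter to 6807 with library size only, and from 4755 without PDT replicate 1 to 6877 without PDT replicate 3. No called gene took the opposite sign in a setting chosen before, while 258 did with offsets, 33 of them called. Of 173 called genes that the naming rule selects, 166 kept their call in each setting chosen before and 155 with offsets, where 4 histone genes had no value. Of 23 called lists, 19 kept theirs in each setting chosen before apart from the 2 other list tests, and 19 with offsets, where the histones had no value. The estimated correlation left 0 lists called, and the cause was not tested. The stricter filter, which tests fewer genes, left 276 genes changed at least 2-fold, against 610. With the replicate number as a block, 6067 genes were called, 3093 higher and 2974 lower, and 5874 of the main calls were kept. Deviations of same-numbered samples correlated across genes with r of -0.012, 0.014 and 0.0047, so the number does not pair the samples. Under the block the CAF markers (adjusted p = 0.096) and iron genes (0.058) were not called, cholesterol synthesis was called (0.05 as rounded), and no other list or named gene changed its call.

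Some lists and genes changed direction of median or test, and the cause was not tested. These were medians of 0 (RLE), -0.01 (stricter filter), 0.01 (block), 0.01 (offsets) and 0.01 (fry) for S phase genes, and -0.03 to 0.05 without single samples. Heat shock genes had 0.06 (library size only), 0.01 (limma-voom), 0.02 (no filter) and 0.07 (offsets), and -0.03 to 0.03 without single samples. Immediate early genes had -0.08 with library size only and -0.22 with offsets. Noncoding RNA hosts had -0.04 (limma-voom) and -0.07 (stricter filter), and -0.06 to -0.01 without single samples. With fry, apoptosis genes were at 0.10. Of the called lists, offsets put the mitochondrially encoded genes at 0.07, from -0.21, and ribosomal proteins at 0.02, from 0.13. They put vesicle cargo at 0, Xiap at 0.11, mt-Nd3 at 0.07 and Rpl27 at -0.01. Low counts limit statements on genes such as Mdk, with 6 to 17 counts per library.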

Other observations

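Among 19 genes of ferroptosis and iron handling, 10 rose and 3 fell in PDT, also when adjusted over the list alone, with a median log2 fold change of 0.12 (0.15 with length and GC offsets). Camera gave adjusted p = 0.036, or adjusted p = 0.29 with an estimated correlation, and the call ended in each fit that left out a sample other than PBS replicate 2 (adjusted p of 0.051 without PBS replicate 1, 0.12 without PBS replicate 3, 0.069 without PDT replicate 1, 0.052 without PDT replicate 2 and 0.052 without PDT replicate 3) and with the stricter filter (0.081). The median of the list was 0.07 without PBS replicate 3 or without PDT replicate 1, and 0.14 without PBS replicate 1. The ferritin subunit genes Fth1 and Ftl1, which store iron, rose 1.78-fold and 1.75-fold, to 3597 ± 229 and 3302 ± 193 CPM (SD, n = 3). Both have processed pseudogenes and uncertain levels. The iron transporter gene Slc11a2 rose by 0.80 ± 0.05 (SE) and Cisd1, which encodes a mitochondrial iron-sulfur protein, by 0.61 ± 0.06. The transferrin receptor gene Tfrc, chosen after its values were seen, fell from 141.1 ± 13.7 to 96.8 ± 2.11 CPM.

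Wnt and Notch target genes were not called as a list, with 2 of 19 higher and 5 lower over all genes and over the list alone (median -0.06, mean -0.46, camera adjusted p = 0.12). The Notch target Hes1 fell 3.91-fold from 24.5 ± 0.88 to 6.27 ± 0.51 CPM, the Notch ligand gene Jag1 fell 2.45-fold, and the Wnt target Ccn4 fell 2.72-fold from 192.3 ± 3.34 to 70.8 ± 0.47, while Sfrp1 rose by 0.42 ± 0.04. Immediate early genes were divided, with 11 of 29 higher and 10 lower (11 and 11 adjusted over the list alone; median -0.13, mean -0.11, test direction higher, camera adjusted p = 0.86). Egr1 fell by 1.41 ± 0.07, and Maff, Jund and Fosl1 rose by 0.89 ± 0.06, 0.76 ± 0.05 and 0.75 ± 0.06. Markers of chondrocytes and osteoblasts had 5 of 7 tested members lower and 1 higher, also over the list alone (median -0.60, -0.55 with offsets, camera adjusted p = 0.0032; adjusted p = 0.25 with an estimated correlation), and Col2a1, Col10a1, Dmp1 and Sox9 fell (log2 fold changes of -1.53 ± 0.05, -1.73 ± 0.12, -1.63 ± 0.14 and -0.45 ± 0.04). Skeletal muscle markers had 4 of 7 lower and 1 higher, also over the list alone (median -0.62, -0.77 with offsets, camera adjusted p = 0.021; adjusted p = 0.25 with an estimated correlation, and 0.052 without PDT replicate 3). Tnnt2, Acta1 and Mef2c fell (-2.05 ± 0.14, -1.16 ± 0.15 and -0.34 ± 0.05; Mef2c at adjusted p = 0.458 with offsets), and Mylpf rose by 1.44 ± 0.26 from 0.32 ± 0.06 CPM. Adipocyte markers had 3 of 6 higher and 0 lower, also over the list alone. Their median was 0.44 (0.46 with offsets), with camera adjusted p = 0.023 and adjusted p = 0.25 with an estimated correlation. The adipogenic regulator gene Pparg, the lipid droplet gene Plin4 and Fabp4 rose by 0.50 ± 0.05, 0.49 ± 0.03 and 0.39 ± 0.08. Of 15 chondrocyte and osteoblast, 16 skeletal muscle and 13 adipocyte markers on the lists, only 7, 7 and 6 were tested. Mean levels of Myod1, Myf5 and Myog were 0 CPM in both groups, and those of Sp7 and Adipoq were at most 0.0314 CPM. These 3 list results therefore rest on few members and do not show a change of cell type.

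The tests of the 3 patterns that follow were all chosen after the results were seen, and the count of other splits before. Of the 10 ways to divide the 6 libraries into 3 and 3, only 1, the real one, gave as many changed genes (6372, highest other 2), as many higher (3294, highest other 1), lower (3078, highest other 1) or changed at least 2-fold (610, highest other 2), or as many called lists (23, highest other 13). With 10 splits the share cannot fall under 0.05. Each other split mixes PBS and PDT libraries in both groups, so the difference between PBS and PDT adds to the spread within groups. The few genes called there therefore do not measure how many calls chance would give.

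Long and AU-rich transcripts were lower in PDT. The trend was also present outside the fixed lists, with a rho of log2 fold change with length of -0.35 over 8419 of 9172 genes. So few genes were left out that the rho could hardly have changed, so this does not weigh the listed genes as a cause. A difference in library or RNA quality that need not follow the treatment is a candidate explanation. PDT replicate 3 deviated from the other PDT libraries along length with a rho of 0.5 and along GC with -0.37. The trend against PBS was weaker in replicate 3 (-0.23) than in replicates 1 and 2 together (-0.39). Over 5493 changed genes replicate 3 also had smaller fold changes (slope of 0.835, against 1.05 and 1.07 for replicates 1 and 2). Its deviation therefore does not separate a quality difference from a weaker response in that replicate. Along GC the trend differed less, with 0.32 in replicate 3 and 0.40 in the others, and among the PBS libraries only replicate 2 deviated from its group with opposite signs along length and GC (-0.18 and 0.20), while replicate 1 had 0.23 and 0.19 and replicate 3 had -0.06 and -0.35. A shift of RNA composition after treatment stays open and was not tested separately.

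TGF-β direct target genes were lower in PDT. The length and GC trend does not account for this, since with offsets the median was -0.54 against -0.47 without them. The choice of RLE or library size only in place of TMM does not either, since the median nearest to 0 was -0.42, with library size only. These choices shifted the median of all genes by only -0.009 and 0.049, and larger differences in scaling were not tested. An effect of PDT stays open, and vesicles, dye and light were not tested apart. All samples were given TGF-β, so whether the lower levels reverse its effect cannot be told.

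NF-κB and inflammatory genes were higher in PDT. Leukocytes among the cultured cells would bring their own abundant transcripts, but Ptprc and Tyrobp had 0 counts in all 6 libraries. The summed level of 14 leukocyte markers rose by at most 0.5% of the rise of the chemokine gene Ccl2. Ccl2 lay between 234 and 277 CPM in PBS and between 599 and 634 in PDT, scaled by library size. It was chosen after its values were seen, and a less abundant gene would give a larger share. Most of the marker sum was Cd14, with a mean of 10.5 CPM in PBS and 11.3 in PDT. The share is therefore a description against Ccl2 and does not by itself weigh leukocytes as a cause. Lyz2 lay between 0.14 and 0.16 CPM in PBS and between 0.23 and 0.31 in PDT, higher in all 3 PDT libraries but not called (adjusted p = 0.121). The length and GC trend does not account for the rise, since the median with offsets was 0.48. An effect of PDT on the fibroblasts stays open and was not tested apart from these.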
